A study of Sus scrofa with 16 samples.

How the data were processed

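Reduced representation bisulfite sequencing (RRBS), which reads cytosine methylation in CpG-rich fragments cut by a restriction enzyme, was applied to genomic DNA of LD muscle from 16 newborn male piglets. Per the labels' protocols, DNA was extracted by salting out and libraries were made with the NuGEN Ovation RRBS Methyl-seq kit. Trim Galore (version 3), Bismark, Bowtie2 (version 2.2.2) and methylKit are named in the submitters' processing notes, with no role, order or parameter, so filters and trimming settings are not given in the sources used here. The genome build is not given in the sources used here either. Positions on chromosome 1 reach 315245536, beyond the last gene end (274280750) of the Sscrofa11.1 gene table at hand, so that table's coordinates were not used and positions are printed as the files give them.

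Each deposited file holds 1 piglet, on chromosomes 1 to 18, with a position, strand, value and read coverage per cytosine. The deposited coverage column is a count of reads, with no normalization. In the 8 control files the deposited value is a fraction, methylated reads divided by coverage: multiplied by coverage it gave whole reads (within 0.001) at 100% of cytosines. In the 8 PRRSV files the deposited value is another quantity, methylated reads divided by methylated reads plus 5: read as a fraction of coverage it gave whole reads at 33.4% to 36.9% of cytosines, and solved for methylated reads by this second formula it gave whole reads at 100%, none above the coverage. These shares were taken at cytosines of up to 200 reads, with the tolerance widened by the rounding of the printed digits in the PRRSV files. The deposited values of the groups are therefore on different scales, and methylated reads were recovered from each file with its own formula before any comparison. At 8 to 94 very deep cytosines per PRRSV file the printed digits leave the read count uncertain. No source used here describes the second formula.

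A cytosine on the forward strand and its partner 1 position further on the reverse strand were combined into 1 CpG. The strands gave correlated levels where both had at least 10 reads, with Pearson correlations across CpGs of 0.963 to 0.969 in the 16 libraries (CpGs are not independent replicates). CpGs with at least 10 reads in at least 6 of the 8 piglets of each group were tested. Coverage summed over cytosines was 38395977 to 51239405 per piglet. PCR duplicates cannot be told from separate molecules in these files, so read-based intervals cover counting error only.

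Groups were taken from the title and source name. The maternal infection entry of the labels states the opposite in all 16 samples, so every direction below reverses if that entry is the right one. The 8 control piglets came from 3 gilts and the 8 PRRSV piglets from 2 gilts, and the labels do not tie piglets to gilts. Siblings could thus not be blocked, p-values over piglets may be too small, and an exact test of 3 against 2 litters could not go below p = 0.1.

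Mean methylation was compared with a two-sided exact permutation test of piglet means, whose smallest possible p is 0.000155. Confidence intervals (95%) were obtained by inverting that test. Chromosomes were compared in the same way with Benjamini-Hochberg adjustment over the 18. Single CpGs and 1000 bp tiles with at least 3 CpGs were tested with a quasi-binomial logistic model of methylated and unmethylated reads (Pearson overdispersion of at least 1, F test). Calls needed a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 10 percentage points. By a rule set in advance, the text names the 5 called CpGs with the largest increase, the 5 with the largest decrease, and the called tiles. Differences are PRRSV minus control from pooled reads, with the model's standard error (SE), while group levels are means of piglets with their SD. The design, the groups, this rule and most alternatives were set before the data were examined. Recovery of reads from the second formula, classes of CpG density and of methylation level, and the alternatives named as later additions in the closing section were not.

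The tests of promoters, gene bodies and gene lists that the design also planned were not run, because no annotation of the files' build was used here. Fixed lists of genes were therefore not tested, and the text names positions, not genes.

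The model was tested on simulated reads with the real coverages and overdispersion. Changed CpGs and tiles were drawn from intermediate pooled levels, so the shares called do not describe those near either end of the range. Among 1234806 simulated CpGs, 0 of 50 CpGs changed by 10 points and 0 of 50 changed by 25 points were called, against 22 of 50 changed by 50 points and 36 of 50 changed by 60 points, with 0 unchanged CpGs called. Among 106551 simulated tiles, 8 of 100 changed by 10 points and 67 of 100 changed by 25 points were called, with 1 unchanged tile called. Alternatives were other coverage minimums, CpGs covered in all piglets, thinned reads, removal of variant-like or very deep CpGs, a read-weighted mean, a binomial model, limma's moderated test on percent methylation, other minimum differences, and each piglet left out in turn. To count as variant-like, a CpG needed every piglet within 10 points of 0%, 50% or 100%. Counting error at the depths of the called CpGs can move a level further than that. The filter could thus miss variants and cannot clear a called CpG of one. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. limma's test was recomputed in Python and checked against limma 3.58.1.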

Results

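DNA methylation was measured by RRBS in LD muscle of 16 male piglets sampled at birth. Gilts had received porcine reproductive and respiratory syndrome virus (PRRSV, an arterivirus of pigs) or sterile medium through the nose on gestation day 80, and the piglets themselves were labelled uninfected. The control group held 8 piglets of 3 gilts and the PRRSV group 8 piglets of 2 gilts. The design asks whether viral infection of the mother goes with altered methylation in the skeletal muscle of her offspring. The labels contradict each other on which group was exposed, and the groups here follow the titles. The files covered 5629631 to 6351159 cytosines per piglet. Mean coverage per cytosine was 7.45 ± 0.35 reads in controls and 7.86 ± 0.22 in PRRSV piglets (SD, n = 8 each; two-sided exact permutation p = 0.0126), so the PRRSV libraries were somewhat deeper. No library was a copy of another: pairs had a mean chi-square per CpG of 1.48 to 2.94, where counting error alone gives 1 and separate animals or duplicate reads give more.

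Newborn muscle showed the same broad methylation landscape in both groups. Of 1234806 CpGs tested, 42.3% had a mean level below 10%, 19.9% a level above 90%, and 37.8% a level between. Methylation fell with local CpG number: in controls, CpGs in tiles with 1 to 9 tested CpGs averaged 66.3% ± 1.9 and those in tiles with 60 or more averaged 5.90% ± 0.19 (SD, n = 8), against 66.9% ± 1.3 and 5.96% ± 0.20 in PRRSV piglets. Chromosome 11 was the most methylated (53.9% ± 1.7 in controls) and chromosome 14 the least (35.9% ± 1.8).

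Mean methylation over the tested CpGs was 41.8% ± 1.8 in controls and 42.3% ± 1.4 in PRRSV piglets (SD, n = 8 each). The difference of 0.451 points (95% interval -1.16 to 2.24) did not exceed the spread between piglets (two-sided exact permutation p = 0.611). Over the 766806 CpGs covered in all 16 piglets the levels were 35.1% ± 0.42 and 35.5% ± 0.38, a difference of 0.349 points (-0.0705 to 0.778, exact p = 0.1004). All 18 chromosomes had a higher mean in the PRRSV group, by 0.280 to 0.667 points, and none passed (exact permutation tests, adjusted p = 0.726 for each). Over the CpGs covered in all piglets, chromosome 11 differed most, with 47.5% ± 0.51 in controls and 48.1% ± 0.47 in PRRSV piglets (exact p = 0.0289, adjusted p = 0.19). The chromosomes were read in the same 16 libraries and are not independent. Among the density classes no difference passed either (lowest adjusted exact p = 0.834 over all tested CpGs and 0.199 over those covered in all piglets). CpGs with a mean above 90% had 94.4% ± 0.16 in controls and 94.6% ± 0.18 in PRRSV piglets (exact p = 0.0488, adjusted p = 0.146 over 3 level classes), and over those covered in all piglets 94.3% ± 0.14 and 94.5% ± 0.17, a difference of 0.199 points (unadjusted interval 0.0334 to 0.361, exact p = 0.0232, adjusted p = 0.0695). The intervals of the mean over all tested CpGs leave room for a shift of up to about 2.24 points. Without control 38 the sign of the mean difference turned (-0.217 points, exact p = 0.731).

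**Figure D1:**
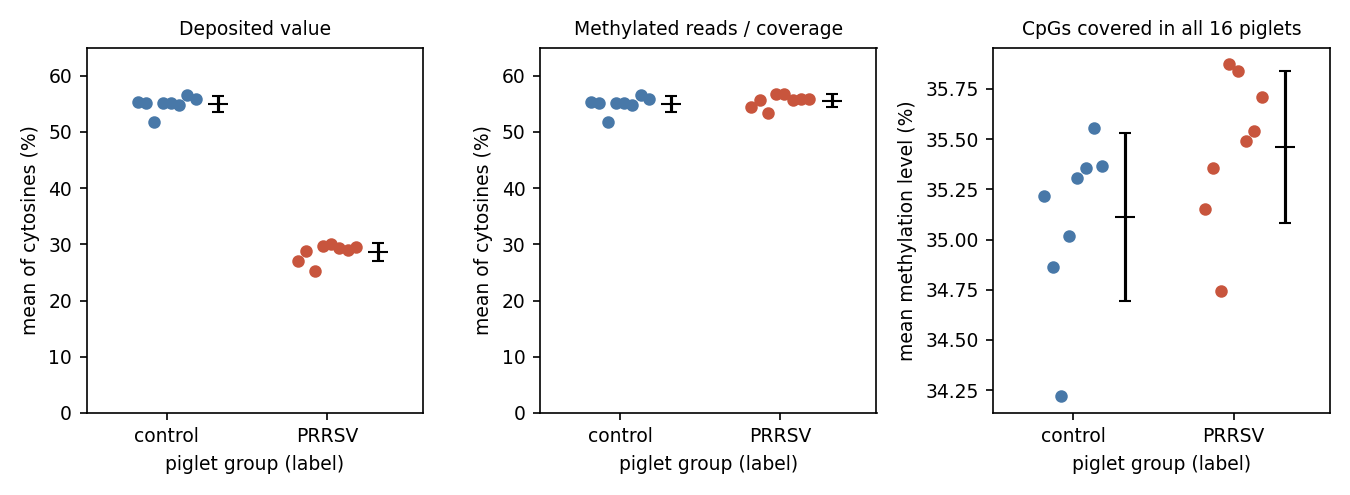
Mean methylation of each piglet (points) with the group mean and SD (bar beside them, n = 8 per group), in percent. The left panel shows the value column as deposited, the middle panel methylated reads over coverage, and the right panel the CpGs covered in all 16 piglets on an axis that does not start at 0. The gap of the left panel (54.95% against 28.58%) is not seen in the middle panel (54.95% against 55.59%).

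**Figure D2:**
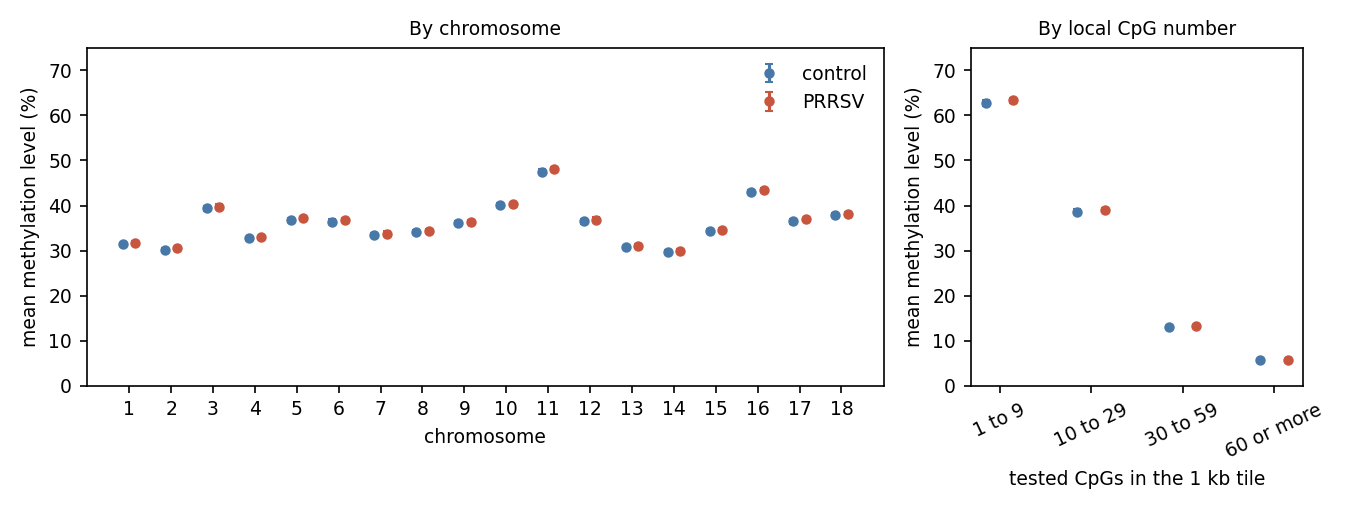
Mean methylation (percent) of control and PRRSV piglets by chromosome (left) and by number of tested CpGs in the 1 kb tile (right), over CpGs covered in all 16 piglets. Points are group means of 8 piglets and bars the SD, mostly smaller than the points. Groups differ little beside the differences between chromosomes and density classes.

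Few single CpGs were called, and their differences were large. The simulation called 0 of 50 CpGs of intermediate level changed by 25 points, so smaller differences could be missed and the calls had to be large at such levels. Of 1234806 CpGs, 19 were called, 5 higher and 14 lower in PRRSV piglets, with differences of 28.0 to 73.3 points. The 4 CpGs with the largest increase all lay on chromosome 10. At position 21662751, methylation was 23.3% ± 15.2 in controls and 91.9% ± 3.5 in PRRSV piglets (SD, n = 8 each), and at position 2057164 it was 26.6% ± 18.0 and 91.8% ± 3.7. Position 16912993 had 39.9% ± 5.7 (n = 8) and 94.4% ± 4.1 (n = 7), and position 13378694 had 37.6% ± 8.9 and 83.6% ± 6.8 (n = 8 each). On chromosome 7, position 123829850 was nearly unmethylated in controls (0.625% ± 1.8) and at 42.3% ± 12.1 in PRRSV piglets.

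The called CpGs that were lower in PRRSV piglets were mostly near 0 in that group. At chromosome 10 position 3167179 the level was 70.9% ± 14.7 in 8 controls and 0% in each of 6 covered PRRSV piglets. At chromosome 1 position 301126399 it was 66.0% ± 11.7 (n = 8) and 0.794% ± 2.1 (n = 7), at chromosome 3 position 4324796 it was 58.97% ± 6.8 (n = 7) and 0% (n = 7), and at chromosome 8 position 111867007 it was 51.9% ± 8.9 (n = 7) and 0% (n = 8). Chromosome 17 position 32991740 had 96.6% ± 5.5 in controls and 43.4% ± 10.5 in PRRSV piglets (n = 8 each). The other 9 lower CpGs lay on chromosomes 2, 4, 5, 7 and 9, with 3 of them between 71478132 and 71666539 on chromosome 5, 2 of these 4109 bp apart. Across all 14, controls were intermediate and PRRSV piglets near 0 at 10 CpGs, and controls were high and PRRSV piglets intermediate at 4 CpGs.

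In the quasi-binomial model with Benjamini-Hochberg adjustment, the adjusted p of these 10 named CpGs ran from 0.0098 to 0.0219. The largest increase, at chromosome 10 position 21662751, was 73.3 points (SE 4.58), from 401 control and 182 PRRSV reads. The largest decrease, at chromosome 10 position 3167179, was -68.1 points (SE 3.86), from 163 and 107 reads. Where every read of a group was unmethylated, that group adds no spread to the model, so SE and adjusted p may be too small. Among the named CpGs this holds for that position, chromosome 3 position 4324796 and chromosome 8 position 111867007. Among the 766806 CpGs covered in all 16 piglets, the piglets of the groups did not overlap at 156 (0.0203%), where chance gives up to 0.0155% and up to 124 CpGs were seen in 99 other splits of the piglets. With single piglets left out, the calls at chromosome 10 positions 13378694, 16912993 and 2057164 were lost in 8, 7 and 7 of 16 cases, that at chromosome 3 position 4324796 in 8 and that at chromosome 17 position 32991740 in 1. The call at chromosome 10 position 3167179 could be tested in 10 of 16 cases, since 6 PRRSV piglets cover it, and was kept in those. An unadjusted p under 0.05 was found at 48641 CpGs (3.94%), where those other splits had a median of 2.78% and at most 3.71%. Thinning to at most 10 reads per CpG and piglet ended every call, with differences of 17.5 to 71.25 points left, in the same direction, at the 12 named CpGs and tiles. Leaving out 3 libraries together (control 38, PRRSV 16 and PRRSV 19) also ended the calls of the 19 CpGs and of the 2 tiles below, and under that setting the differences of the 12 were 0.945 to 1.07 times those given. The number of calls moved with the model, to 53 with limma (19 higher, 34 lower in PRRSV piglets). A binomial model that ignores overdispersion gave 12313, of which 6645 were higher and 5668 lower, so the balance of directions turned.

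**Figure D3:**
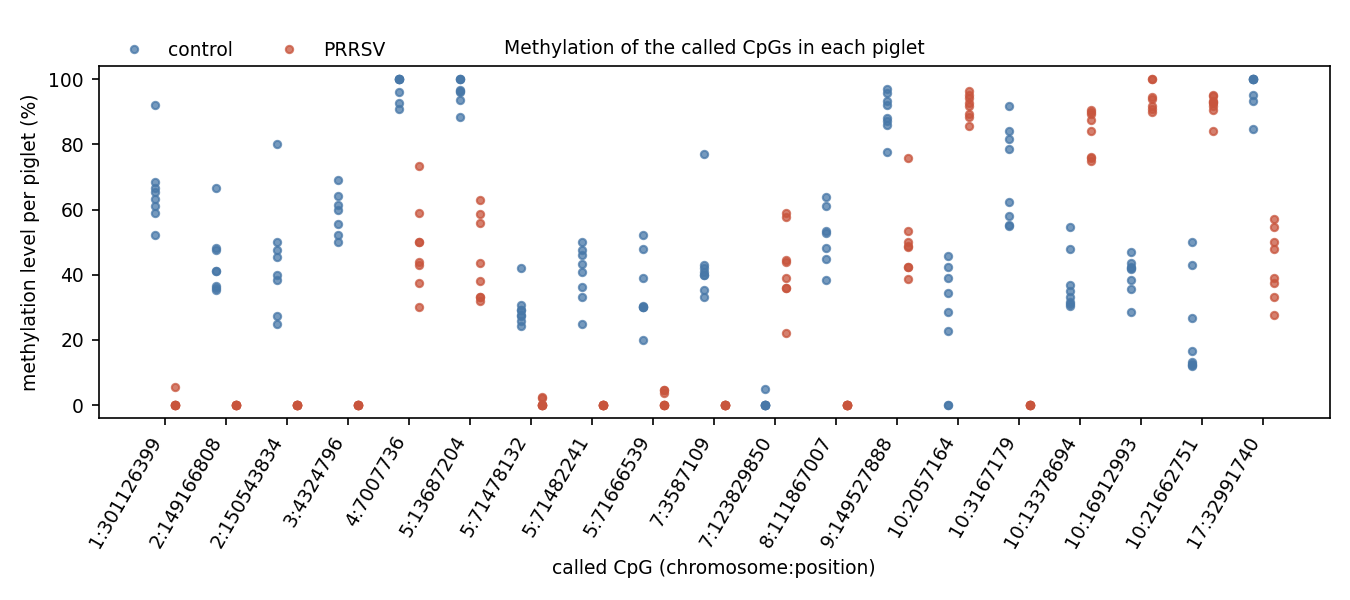
Methylation level (percent) of each piglet at the 19 called CpGs, named by chromosome and position as the files give them. Each point is 1 piglet with at least 10 reads, and the CpGs were picked for their group difference, so that separate points are no evidence of their own.

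Neighbouring CpGs did not follow the called ones in most places. Within 50 bp of the 19 called CpGs lay 53 other tested CpGs, of which 0 were called and 46 differed by less than 10 points. Their median absolute difference was 3.22 points, against 49.7 points at the called CpGs. The most different neighbour lay 5 bp from chromosome 10 position 21662751 and was 32.7 points higher in PRRSV piglets (adjusted p = 0.313 in the quasi-binomial model). The 95% interval of the difference lay within 10 points of 0 at 59.7% of all tested CpGs and within 25 points at 95.3%. It has no width where every read was unmethylated or every read methylated, whatever the depth, so these shares may be too high. At many sites a difference of 10 points could thus not be excluded.

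**Figure D4:**
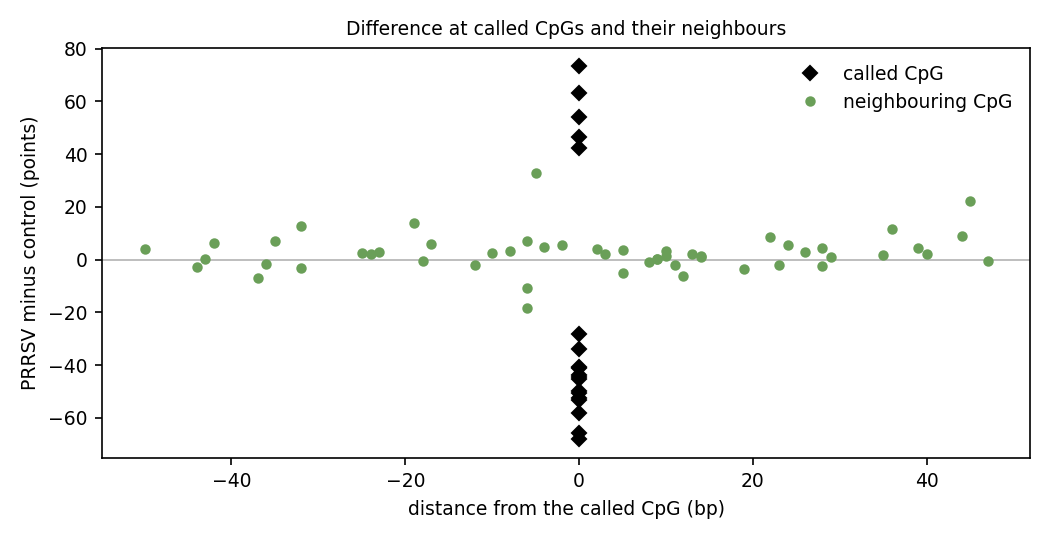
Difference in methylation (PRRSV minus control, percentage points) at the 19 called CpGs (diamonds) and at the 53 tested CpGs within 50 bp of them (circles), against distance in bp. The neighbours sit mostly within 10 points of 0.

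At the level of 1 kb tiles, 2 of 106551 regions differed. Chromosome 10 from 21662001 to 21663000 (3 CpGs) had 48.7% ± 11.2 in controls and 88.5% ± 2.9 in PRRSV piglets (SD, n = 8 each), and chromosome 5 from 13687001 to 13688000 (3 CpGs) had 94.0% ± 2.5 and 71.0% ± 7.3. The model differences were 42.8 points (SE 3.18, adjusted p = 0.00258) and -22.4 points (SE 2.48, adjusted p = 0.0187). Each tile holds 1 of the called CpGs. With it left out, the chromosome 10 tile differed by 24.4 points (SE 3.29) and the chromosome 5 tile by -3.21 points (SE 2.68), and with all called CpGs left out 0 tiles were called. The call of the chromosome 5 tile was lost in 6 of 16 cases with a single piglet left out, that of the chromosome 10 tile in 0. An unadjusted p under 0.05 was found at 7794 tiles (7.31%), and limma called 16. When only CpGs covered in all 16 piglets entered, 12 tiles were called.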

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

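The tests on control 38 were chosen after its values were seen, and so were the tests of tiles without their called CpG, of chromosome 10 and of depth in a model; the tests of neighbouring CpGs, thinned reads, reference sequence and other splits were set before. Values standing apart from the rest of their group of 8 were found 13 times in 75 groups examined, where chance gives about 1 in 20 groups. Most of the 13 are overlapping summaries of the library of control 38. The groups are thus not independent, and the count does not show a general excess.

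Control 38 had the lowest mean methylation of its group, 37.4% against 42.0% to 43.2% in the other 7 controls. It stood apart in tiles with 1 to 9 CpGs (61.8%), 10 to 29 CpGs (39.0%) and 30 to 59 CpGs (13.3%) and at CpGs of 10% to 90% mean level (57.5%). Over CpGs covered in all piglets it stood apart on chromosomes 8 (33.5%), 13 (29.9%), 14 (28.9%) and 16 (42.0%). At CpGs above 90% it was also the lowest control (93.7% against 93.9% to 94.3%), by 0.397 points from the median of the other controls. A loss of several points at highly methylated CpGs in this library is thus argued against, while a small one is not. A candidate explanation is that fewer methylated CpGs reached 10 reads: 23.5% of them were missing in control 38 against 2.67% to 12.3% in the other controls, and over CpGs covered in all piglets 21.9% of its distance remained (1.08 of 4.96 points), which leaves a part unaccounted for.

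Single piglets stood apart at 4 named CpGs. PRRSV 20 had 84.0% (21 of 25 reads) at chromosome 10 position 21662751, where the other PRRSV piglets had 90.5% to 95.2%. Control 51 had 5% at chromosome 7 position 123829850, where the other controls had 0%; this is 1 methylated read of 20, and with the others at 0 any such read stands apart, so it says nothing about this piglet. Control 51 also had 92.0% (23 of 25 reads) at chromosome 1 position 301126399, where the others had 52.2% to 68.4%. Control 38 had 84.6% (11 of 13 reads) at chromosome 17 position 32991740, where the others had 93.3% to 100%. Counting error at these depths can move a level as far as those of PRRSV 20 and control 38. Neither value thus needs a difference of the piglet.

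The 19 called CpGs and 2 called tiles showed large differences that neighbouring CpGs mostly did not share. Alignment of the groups to different references is argued against, since 0.00928% of CpGs (140 of 1508124) read in one group had no read in the other. A difference in depth is argued against for the 19 CpGs as a set. With each piglet's log2 reads in a linear model, the differences were a median of 1.01 times those without (0.752 to 1.06 over the 19). The lowest was at chromosome 10 position 21662751, the CpG with 401 control and 182 PRRSV reads, at 51.6 points (SE 4.66) against 68.6 between the group means. There, controls with 53 to 75 reads had 12.0% to 16.7%, and controls with 21 to 30 reads had 26.7% to 50%. PRRSV piglets had 15 to 29 reads. Depth and group are hard to tell apart at this CpG, so a part played by depth stays open there. Thinned reads also kept a median of 50 points, as they would by design, and decide nothing; the calls ended there with fewer reads. With piglets taken as independent, chance is argued against for the CpGs (19, at most 4 in the other splits, 1 of 100 splits reaching 19). Siblings are not independent, so chance differences among litters are not excluded. An exact test of 3 against 2 litters could not go below p = 0.1. Another split also gave 2 tiles (2 of 100 splits reaching 2, at most 2 in the others). No split separates exposure from litter or processing. Sequence variants shared by siblings stay open. They would leave neighbours unmoved, as most were (median ratio -0.0109, interval -0.0554 to 0.0371). Many neighbours belong to the same called CpG and are not independent, so this interval may be too narrow. Some neighbours moved in the called direction, such as 32.7 and 11.8 points beside chromosome 10 position 21662751 and -18.2 beside 3167179. Others moved against it, such as 22.1 points beside chromosome 2 position 150543834 and 14.0 beside chromosome 5 position 71666539, both called lower. Chromosome 10 held 5 calls, between 2057164 and 21662751, where 0.609 were due (exact binomial p times 18 = 0.00487), a test prompted by those calls. A variant segregating among siblings could spread piglets over about 0%, 50% and 100%, but need not. A uniform level within a group thus does not argue against a variant. At chromosome 5 position 71478132 all 8 controls had 24.2% to 42.1%, while at chromosome 10 position 2057164 they ran from 0% to 45.7%. That spread was not tested. The chromosome 5 tile may rest on its called CpG alone (-3.21 points without it), while the chromosome 10 tile still differed without its own (24.4 points, SE 3.29). The other CpGs of the chromosome 10 tile, at 21662746 and 21662787, lie within 50 bp of the called one and may share its reads. A part played by depth thus stays open for that tile too. An effect of maternal infection stays open at all of these sites and cannot be told apart from litter. Nor can it be told from a processing difference between the groups. All 8 PRRSV files hold another value formula, and mean coverage differed (exact permutation p = 0.0126).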

How the results depend on the processing

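The use of the deposited values as they stand, libraries left out together and tiles without called CpGs were added after seeing the data. With the deposited values as they stand the mean difference reversed to -7.54 points (exact p = 0.000155, the smallest possible), and 453702 CpGs and 60660 tiles were called, by construction of the differing formulas. CpGs called numbered 33 at a coverage minimum of 5 (18 of the 19 among them), 7 at 20 (where 7 of the 19 were testable and 6 of these were called), 0 after thinning to at most 10 reads, 12313 with the binomial model and 53 with limma. Tiles called numbered 1 at a coverage minimum of 20 (another tile, since neither reported tile was testable), 12 with CpGs covered in all piglets, 0 after thinning, 2018 with the binomial model, 16 with limma, 1 at a minimum difference of 25 points, and 0 without called CpGs. Fewer reads per CpG lie behind the loss under thinning; the cause of the other changes was not tested. Leaving out control 38, PRRSV 16 and PRRSV 19, the libraries with the largest shortfall of methylated CpGs, and asking for 5 piglets per group, gave 0 CpGs, 1 tile, which is neither of the 2 reported ones, and a mean difference of 0.716 points (exact p = 0.0186). Those are also the 3 libraries with the lowest mean methylation, 1 control and 2 PRRSV, so that p is chosen by the outcome and is not evidence of a shift. The mean difference was 0.427 points at a coverage minimum of 5 (exact p = 0.565) and 0.0318 at 20 (exact p = 0.962). With methylated reads over all reads it was 0.129 points (exact p = 0.931). Without each piglet in turn the mean difference ran from -0.217 (without control 38, reversed) to 0.920 points, called CpGs from 12 to 29 and called tiles from 1 to 11. CpG calls moved by over 1.5 times without control 9 (29), PRRSV 19 (12) and PRRSV 23 (12). Tile calls moved without control 1 (4), control 9 (11) and PRRSV 26 (5), and to 1 without controls 43, 46 or 49 or PRRSV 18, 19 or 23, where the chromosome 5 tile lost its call. The 12 named CpGs and tiles reversed in none of the settings run. They lost their call in 14 of 105 values under the other settings (12 of them after thinning), in 37 of 186 values without single piglets and in 12 of 12 without the 3 libraries, where their differences were 0.945 to 1.07 times the reported ones, such as 71.9 against 73.3 points at chromosome 10 position 21662751 and 43.7 against 42.8 for the chromosome 10 tile (adjusted p = 0.0693). Removing 568 variant-like CpGs ended 0 calls and decides nothing. No paired analysis was possible because the groups share no replicate numbers. Promoters, gene bodies and gene lists were not tested under any setting, for want of an annotation of the build. Of 50 simulated CpGs of intermediate level changed by 25 points, 0 were called. The simulation kept the real coverages, number of piglets and adjustment, so it cannot tell which of these was the limit. It does not describe CpGs near either end of the range, where a difference of 28.0 points was called at chromosome 5 position 71478132.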

Other observations

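The values below were looked for after the data were seen, except the test of median coverage in tiles of intermediate methylation.

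Several 1 kb tiles with many CpGs differed without passing the main test. On chromosome 6 from 100882001 to 100883000, 14 CpGs had pooled levels of 16.8% in controls and 6.19% in PRRSV piglets (-10.6 points, SE 1.56, adjusted p = 0.0687 in the quasi-binomial model). Over the 13 of these CpGs covered in all piglets every CpG was lower in the PRRSV group, the tile was called (adjusted p = 0.0462), and the rest differed by -9.07 points (SE 1.49) without its most different CpG. On chromosome 12 from 62686001 to 62687000, 44 CpGs had 25.3% and 13.3% (adjusted p = 0.0885). On chromosome 11 from 38081001 to 38082000, 40 CpGs had 80.7% and 85.3% (4.57 points, SE 0.63, adjusted p = 0.0687). Of the 12 tiles called over CpGs covered in all piglets, 1 still differed by at least 10 points without its most different CpG, on chromosome 10 from 21662001 to 21663000. Among these 12 were 3 within chromosome 15 from 134434001 to 134643000, 2 of them higher and 1 lower in PRRSV piglets.

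Some tiles were near the middle of the methylation range in every piglet. Of 34715 tiles with at least 10 CpGs, 695 (2.00%) lay between 35% and 65% in all 16 piglets. The tile with most CpGs, on chromosome 1 from 9247001 to 9248000, held 67 CpGs at 54.8% in controls and 51.7% in PRRSV piglets. Collapsed repeat copies are argued against for these tiles as a set by a median coverage per CpG 0.996 times that of the other tiles. For the 17 with at least 1.5 times the others' median coverage (2.45% against 1.26% of the others, 1.94 times) collapsed copies stay open, such as chromosome 6 from 859001 to 860000 at 1886 reads per CpG and chromosome 17 from 69496001 to 69497000 at 1130.3. A location near chromosome ends may be part of the pattern, since 73.1% of these tiles lay in the outer 10% at either end of a chromosome against 49.9% of the others (1.46 times). No biological explanation, such as parent-of-origin methylation, was tested, since the groups give none.

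More CpGs were read in one group and had no read in the other than in the other 99 splits of the piglets, 140 against at most 72. The share of CpGs with an unadjusted p under 0.05 was 3.94% in the real split and at most 3.71% in the others, and for tiles 7.31% and at most 6.88%. Over the 76681 most variable CpGs covered in all piglets, correlations of deviations from the mean had a median of -0.0138 (-0.211 to 0.197) for 56 pairs of one group and -0.123 (-0.263 to 0.049) for 64 pairs across groups, taken across CpGs, which are not independent. With no structure among 16 piglets such correlations are expected at -0.0667.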
